A study of Mus musculus with 6 samples.

How the data were processed

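Polyadenylated RNA of 3 untreated and 3 budesonide-treated samples of E14 gastruloids was sequenced from stranded mRNA libraries, per the labels' protocols. The submitters' processing notes name bcl2fastq, cutadapt 2.5, STAR 2.7.5c, featureCounts 2.0 and DESeq2 and the mouse genome build GRCm39, with no parameters, and the annotation version and the strand setting of the counting are not given in the sources used here. With the strand setting unknown, reads of overlapping genes and antisense partners cannot be told apart, and members of near-identical families such as Zscan4, Usp17l and Rhox can trade reads. The authors deposited a table of raw counts per gene symbol for 53819 symbols, 1 column per library. A further deposited table holds a normalized signal for 33560 genes: checked against the counts, each value was the count divided by 1 factor per library, to within 0.0381 reads in every value (tolerance 0.05 reads), and the factors were DESeq2 size factors. Genes with a total of at most 10 reads were left out of that table. Genes are named as in the tables, and 92.8% of the symbols (97.3% of the tested genes) occur among the GENCODE M21 gene names. No coordinates were used, because the reference in hand was of another build.

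Groups and replicate numbers came from the sample titles. Libraries held from 5666168 to 7476862 counted reads, and 3 reads in a library correspond to 0.422 to 0.552 CPM, so genes near that level are measured poorly. Libraries of the same group were compared by a chi-square test of their counts and differed by 1.43 to 3.14 per gene (1 would be sampling noise), so none was a repeat of another. Tests used edgeR 4.0.16 in R 4.3.3 on the raw counts: genes kept by filterByExpr (minimum count 10, minimum total 15), TMM scaling, robust dispersion and quasi-likelihood fits with group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. The fitted common dispersion corresponds to a coefficient of variation of 5.73% between libraries of a group. Log2 fold changes are budesonide over untreated. Their standard errors were derived from the quasi-likelihood F statistic. Means and SDs are of TMM-scaled CPM, n = 3.

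Before the data were examined, 40 gene lists were fixed, of which 38 had at least 5 tested genes. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list, with Benjamini-Hochberg adjustment over the lists. A total of 13 lists were called, 5 higher and 8 lower. Only 1 of these, the neuromesodermal and tailbud list, was also called with an estimated correlation. Adjusted p-values rose in that setting also for lists with an estimate near or below 0.01, so a lost call there does not by itself mean correlated genes. Counts of genes rising or falling were also adjusted over the list alone and were the same where no other number is given. Median, mean and camera direction differed in sign for epithelial regulators, steroid receptors, FGF and ERK targets and hypoxia and glycolysis, none of them called.

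Genes were named by a rule also fixed beforehand: 22 chosen anchor genes (19 had enough reads for a test); the 5 largest rises and 5 largest falls among changed genes with a mean of at least 5 CPM, separated groups and a proper gene symbol; and, as examples for a list, up to 2 risen and 2 fallen members with the smallest adjusted p and a mean of at least 1 CPM. Genes named otherwise are said to be so, and some genes that the rule takes are not reported here.

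The gene tests were first tested on simulated counts for the comparison of budesonide with untreated, drawn from the real means and library sizes of 17155 genes. Of 50 genes changed at each fold, edgeR recovered 38% at 1.25-fold, 70% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 9 false calls. The changed genes were drawn only from those with a mean of at least 5 CPM, so recovery below that level was not measured. With no gene changed it made 1 call. A planted list was called by camera and 0 of 20 random lists were. Genes were simulated as independent of each other, and only the planted genes changed. The random lists therefore cannot show how often camera would call lists of correlated genes.

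The alternatives were DESeq2 1.42.0, RLE size factors, upper quartile scaling, no filter on low counts, a filter at 1 CPM in 3 libraries (meant to be stricter, but it kept more genes than filterByExpr), the replicate number as a block, limma on log2 of the deposited normalized counts plus 1, each library left out in turn, an adjusted p under 0.01, glmTreat against a fold of 1.5, camera with estimated correlations, fry, and camera without the 52 genes that stand in more than 1 list. For DESeq2, lists were tested with camera on its Wald statistics. After seeing the data, a fit with offsets for GC content and transcript length was added (from the longest GENCODE M21 transcript of each gene, given for 97.3% of the tested genes), and a fit with no scaling factors. Figures were drawn with matplotlib from the same values.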

Results

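Gene expression was measured by mRNA sequencing in 3D gastruloids, aggregates of mouse embryonic stem cells (ESC line E14) that, left to develop, break symmetry and form a posterior pole with primitive streak and tailbud gene activity. There were 3 untreated libraries and 3 libraries from aggregates treated for 80 h with budesonide, a synthetic glucocorticoid. The title of the series links cell-cell adhesion, symmetry breaking and pluripotency, and the comparison asked how budesonide changed the transcriptome of the aggregates. The untreated libraries held 6407369, 7018327 and 6336709 counted reads and the budesonide libraries 7476862, 6965653 and 5666168. The labels do not say whether the untreated aggregates received a vehicle or were collected at the same time as the treated ones, so a difference in either would be part of the comparison. Nor do they say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

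With budesonide 16 of 17 tested genes of the tailbud fell and none rose, and 18 of 21 tested genes of the naive stem cell state rose and 1 fell. By camera the lists gave adjusted p = 3.15e-13 and 1.35e-12, and adjusted p = 0.0424 and 0.112 with an estimated correlation. The posterior transcription factor T (Brachyury) fell from 126.6 ± 8.87 to 2.64 ± 0.589 CPM (reads scaled to library size; mean ± SD, n = 3 per group), which is 48.5-fold lower, and the tailbud factor Nkx1-2 fell from 88.96 ± 2.32 to 3.50 ± 0.477 CPM. The naive pluripotency factors Esrrb and Zfp42 rose 2.95-fold and 2.49-fold, to 284.7 ± 21.5 and 334.2 ± 21.2 CPM. Pou5f1 (Oct4), shared by naive and primed cells, was at 733.9 ± 7.03 CPM without and 776.1 ± 48.1 CPM with budesonide. Its log2 fold change of 0.08 ± 0.05 (SE) did not pass the test (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.290).

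Of 17155 genes tested, 4917 changed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 2601 of them higher and 2316 lower with budesonide. Over 2-fold, 875 genes changed, 282 higher and 593 lower, and over 4-fold 8 rose and 58 fell. Every budesonide library lay on the same side of every untreated library for 39.6% of all tested genes, where chance gives 10%. Among the changed genes, which the same contrast had selected, it was 95.1%. The first principal component of the log2 CPM values separated the groups and held 52.1% of the variance. The share of higher genes among the changed was 52.9%. It was 38.6% when library totals were used with no scaling factors, 43.1% with upper quartile scaling, 60.3% in DESeq2, which called fewer lower genes (1321), and 62.4% with a GC and length offset.

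**Figure D1:**
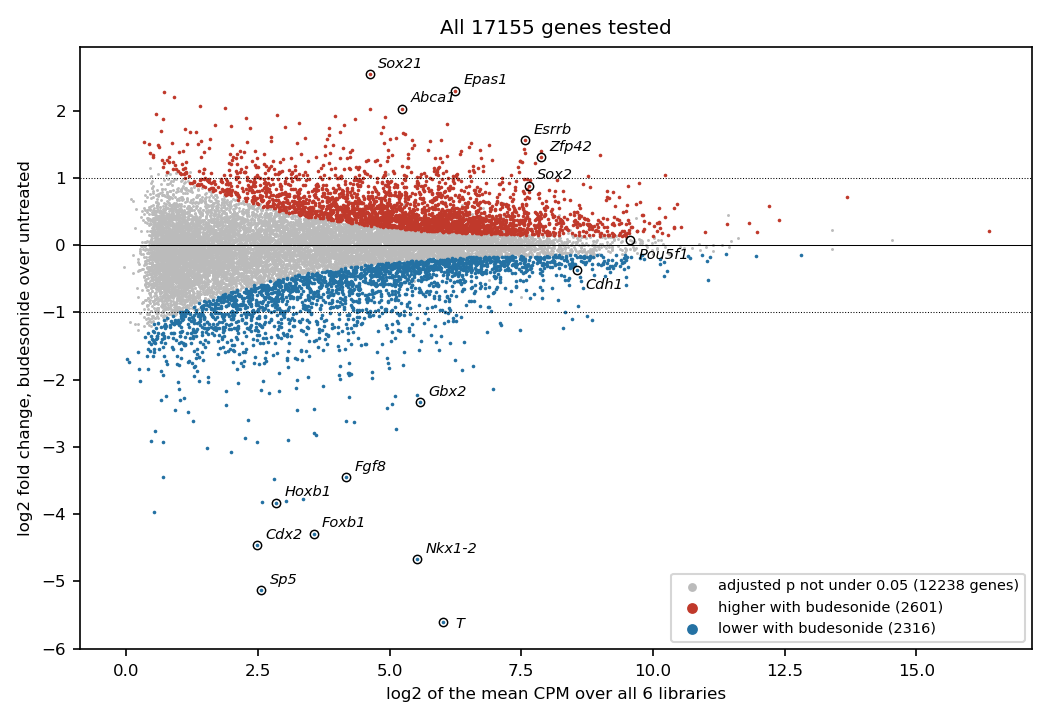
Log2 fold change, budesonide over untreated, of all 17155 tested genes against the log2 of their mean CPM over the 6 libraries. Red points rose (2601), blue points fell (2316), grey points did not pass an adjusted p of 0.05, dotted lines mark 2-fold; T, Sp5, Nkx1-2, Cdx2 and Foxb1 lie lowest among the labelled genes.

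The 5 largest falls among well-expressed genes were T, Sp5 (log2 fold change -5.14 ± 0.36, SE), Nkx1-2 (-4.67 ± 0.13), Cdx2 (-4.46 ± 0.33) and Foxb1 (-4.29 ± 0.24). Sp5 is a transcription factor induced by WNT signalling, and Cdx2 a caudal homeobox factor of the tailbud. The 5 largest rises were Sox21 (2.54 ± 0.13), a SoxB2 transcription factor, Epas1 (2.30 ± 0.09), which encodes the hypoxia-inducible factor HIF-2α, Fabp3 (2.03 ± 0.12), a fatty acid binding protein, Abca1 (2.03 ± 0.11), a cholesterol export pump, and Mymx (1.93 ± 0.22), a muscle cell fusion peptide. In the budesonide libraries Sp5 had 1, 3 and 2 reads and Cdx2 had 2, 4 and 3, so the sizes of their falls rest on few reads. As background, 1469 olfactory and vomeronasal receptor genes averaged 0.555 ± 0.0333 CPM in untreated and 0.553 ± 0.102 CPM in budesonide libraries.

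The genes of the primitive streak, the site where mesoderm forms, fell as a group. Of 12 tested, 11 fell and none rose (median log2 fold change -2.22), and the list was lower by camera, adjusted p = 6.61e-09, with adjusted p = 0.0592 with an estimated correlation. Fgf8, a growth factor of the streak and tailbud, fell from 32.97 ± 3.36 to 3.08 ± 0.903 CPM. Lefty2 was the member that did not pass, at a log2 fold change of 0.05 ± 0.11 (SE; named after its value was seen). Of 17 neuromesodermal and tailbud genes 16 fell and none rose (median -1.69), T and Nkx1-2 most clearly. This list was lower by camera, adjusted p = 3.15e-13, and was the only list of the 38 tested that also passed with an estimated correlation, adjusted p = 0.0424. Its median was -1.03 without genes of more than 1 list.

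All 6 anterior Hox genes tested fell, by a median of -2.84 on the log2 scale (camera adjusted p = 4.86e-06; adjusted p = 0.0662 with an estimated correlation), and the median was -1.86 without a filter on low counts and -1.85 in DESeq2. Hoxb1, a factor that patterns the hindbrain, went from 13.48 ± 1.26 to 0.942 ± 0.188 CPM. Of the trunk Hox genes only 3 had enough reads to be tested, too few for a list test. Hoxa7 fell (-1.01 ± 0.33, SE), adjusted p = 0.0171 by edgeR's quasi-likelihood test, but not in DESeq2 (adjusted p = 0.111), nor without untreated replicate 1 (adjusted p = 0.0533) or budesonide replicate 3 (adjusted p = 0.0770). Adjusted over the list alone, 2 of the 3 fell. Hoxb9 was at 5.38 ± 0.693 and 5.13 ± 0.599 CPM, and no posterior Hox gene of 12 had enough reads.

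Targets of WNT signalling, which drives the streak, fell in 9 of 14 tested cases and rose in 1 (median log2 fold change -0.63; camera adjusted p = 9.55e-06; adjusted p = 0.0705 with an estimated correlation). The feedback gene Axin2 fell from 103.9 ± 3.97 to 38.11 ± 3.36 CPM. Notum, which encodes a WNT-inactivating enzyme, was the member that rose (0.79 ± 0.11, SE). T, Sp5 and Cdx1 are in both this list and the tailbud list. Of 14 NODAL and BMP targets 7 fell and none rose over all genes tested, and 8 fell and 1 rose when adjusted over the list alone (median -0.24, -0.67 without genes of more than 1 list and -0.15 without budesonide replicate 2). Lefty1, a NODAL antagonist, fell 2.24-fold. The list was lower by camera, adjusted p = 0.0483, with adjusted p = 0.256 with an estimated correlation. It did not pass with upper quartile scaling (adjusted p = 0.0594), with no scaling factors (0.0635), with the replicate number as a block (0.0663), or without untreated replicate 1 (0.133), budesonide replicate 1 (0.0730) or budesonide replicate 2 (0.0677).

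**Figure D2:**
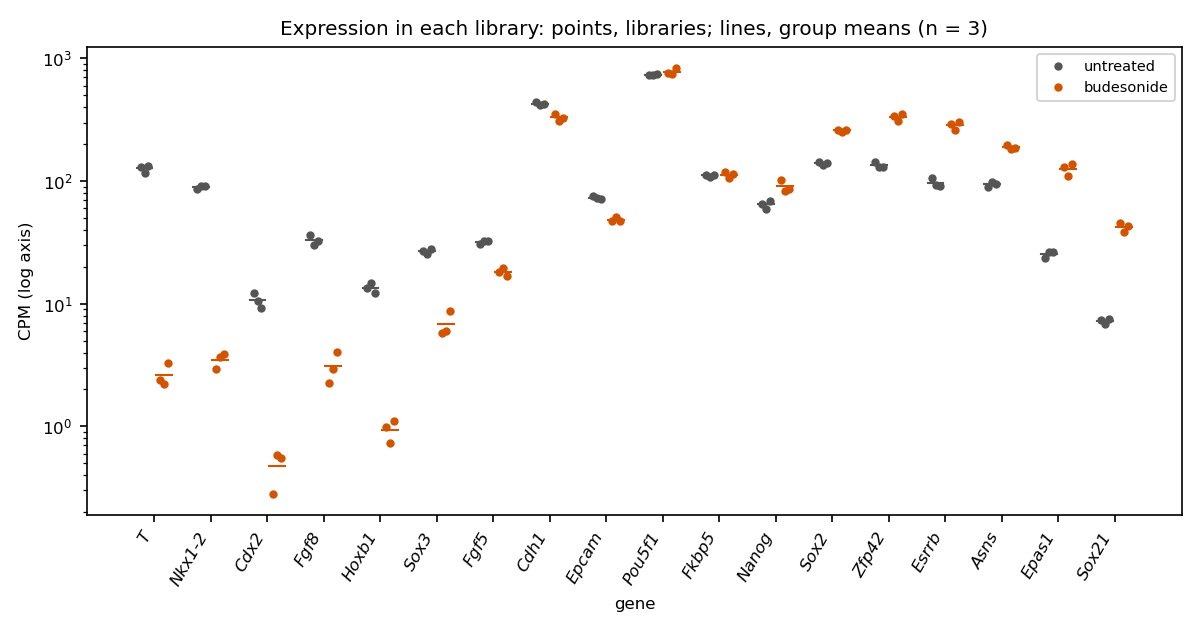
CPM of 18 named genes in each of the 6 libraries on a log axis; points are libraries (grey, untreated; orange, budesonide) and lines are group means, n = 3. T falls from a mean of 126.6 to 2.64 CPM and Sox21 rises from 7.25 to 42.28 CPM, while the points for Pou5f1 and Fkbp5 overlap or lie close together.

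Genes of naive pluripotency, the ground state of ESCs, rose in 18 of 21 tested cases and fell in 1, with 19 and 1 adjusted over the list alone (median log2 fold change 0.99). Zfp57, which protects imprinted DNA methylation, rose from 101.8 ± 4.49 to 273.8 ± 14.2 CPM. Nanog rose 1.41-fold, to 90.55 ± 10.6 CPM, and Klf4 1.51-fold, to 28.28 ± 3.50 CPM. Gbx2 was the member that fell, from 79.36 ± 7.59 to 15.65 ± 0.619 CPM. It is also a gene of the posterior epiblast and the anterior hindbrain. The list was higher by camera, adjusted p = 1.35e-12, with adjusted p = 0.112 with an estimated correlation.

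Core and shared pluripotency genes split. Of 19 tested, 9 rose and 4 fell (10 and 4 adjusted over the list alone; median log2 fold change 0.18, and 0.10 with no scaling factors). Sox2 rose from 140.0 ± 4.48 to 258.7 ± 6.71 CPM and Tet1, a 5-methylcytosine oxidase, from 521.4 ± 7.52 to 957.2 ± 38.8 CPM. The RNA-binding proteins Lin28a and Lin28b, which block let-7 maturation, fell 1.86-fold and 2.13-fold. The adhesion genes Cdh1 and Epcam, given again below, also fell. The list was higher by camera, adjusted p = 0.0356, with adjusted p = 0.321 with an estimated correlation and 0.0531 without budesonide replicate 1.

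Genes of the primed or formative state fell in 10 of 16 cases and rose in 3 (11 and 3 adjusted over the list alone; median -0.41). Fgf5, a marker of the primed epiblast, fell from 31.83 ± 1.04 to 18.12 ± 1.26 CPM, the neural and epiblast factor Sox3 3.98-fold and the DNA methyltransferase Dnmt3b 1.51-fold. Cer1, also among the fallen, lost its call without untreated replicate 1 (adjusted p = 0.0723), and DESeq2 gave it no adjusted p. Otx2, which drives the exit from the naive state, rose 2.27-fold and Dnmt3a 1.56-fold. Camera placed the list lower, adjusted p = 0.0258, with adjusted p = 0.357 with an estimated correlation. The call was lost without genes that stand in more than 1 list (adjusted p = 0.174) and without budesonide replicate 2 (0.0603).

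Germ cell genes rose in 9 of 13 cases and fell in none (median log2 fold change 0.76; camera adjusted p = 0.000194; adjusted p = 0.0705 with an estimated correlation). Sycp3, a protein of the meiotic chromosome axis, rose from 10.65 ± 0.843 to 25.90 ± 4.15 CPM and Stk31, a germ cell kinase-like gene, 2.09-fold. Prdm14 is shared with the naive list. Genes of the 2-cell-like state, a rare ESC state resembling the early embryo, fell in 7 of 8 cases (median -1.56; camera adjusted p = 2.56e-05; adjusted p = 0.0705 with an estimated correlation). Zscan4c went from 3.40 ± 0.286 to 0.660 ± 0.288 CPM and Zscan4e from 3.02 ± 0.926 to 0.241 ± 0.224 CPM. The Zscan4 and Usp17l genes have near-identical copies, so their counts are uncertain. DESeq2 gave neither Zscan4c nor Zscan4e an adjusted p. The 95th percentile of the background receptor genes was 1.83 to 2.21 CPM per library, so the budesonide values of both lie within background. The untreated values of Rhox6 and Rhox9, counted among the risen germ cell genes, also lie within it.

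The adhesion genes did not move together. The epithelial cadherin Cdh1 fell from 425.1 ± 11.3 to 330.0 ± 22.2 CPM (log2 fold change -0.36 ± 0.06, SE; edgeR adjusted p = 1.31e-06) and Epcam from 73.12 ± 1.53 to 48.47 ± 2.26 CPM. Neural cadherin Cdh2 was at 27.30 ± 1.56 and 23.45 ± 2.14 CPM (edgeR adjusted p = 0.171), and passed as lower only with no scaling factors (adjusted p = 0.0456). Of 24 adherens and tight junction genes 5 rose and 7 fell, with 5 and 8 adjusted over the list alone (median -0.12, range -0.19 to -0.07; camera adjusted p = 0.652), where the range, here and below, is that of the median over the alternatives. The plaque protein plakoglobin, Jup, rose 1.72-fold and the tight junction gene Cldn4 2.55-fold, while Nectin2 fell 1.61-fold and cingulin, Cgn, 1.82-fold.

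Desmosome and keratin genes gave 2 rises and 2 falls among 14 (2 and 3 adjusted over the list alone; median -0.19, range -0.31 to -0.07; camera adjusted p = 0.399), with desmoplakin, Dsp, down from 91.90 ± 11.2 to 31.46 ± 3.72 CPM and Krt8 2.47-fold lower. Dsg2, 1 of the 2 that rose, did not pass in DESeq2 (adjusted p = 0.0533). Nor did it pass in edgeR without untreated replicate 1 (0.0533) or budesonide replicate 1 (0.0890). Among 15 epithelial regulators 4 rose and 3 fell (median -0.15, range -0.22 to -0.05; camera adjusted p = 0.907). Klf5 rose from 46.23 ± 4.18 to 92.76 ± 7.83 CPM and Rbm47 2.29-fold, and the splicing regulator Esrp1 fell 1.68-fold. Klf4 and Klf5, both among the 4 that rose, are also naive pluripotency genes counted above. In the list of mesenchymal transition genes 3 of 14 rose and 7 fell (median -0.39, range -0.47 to -0.22; camera adjusted p = 0.108). Fibronectin, Fn1, rose from 780.5 ± 33.1 to 1619.4 ± 108 CPM and Zeb1 2.13-fold, whereas Zeb2 fell 3.19-fold and Tcf4 1.56-fold. Vim fell by 0.19 on the log2 scale (edgeR adjusted p = 0.0359) but did not pass in DESeq2 (adjusted p = 0.245), with limma (0.133), with a GC and length offset (0.0666) or with the filter at 1 CPM (0.0525), nor when any library other than budesonide replicate 3 was left out (adjusted p from 0.0836 to 0.322).

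Collagen genes fell in 7 of 20 cases and rose in none (median log2 fold change -0.43; camera adjusted p = 9.22e-05; adjusted p = 0.256 with an estimated correlation). The basement membrane chains Col4a1 and Col4a2 fell 3.44-fold and 2.48-fold. Of 16 genes of collagen hydroxylation and proline metabolism 2 rose and 6 fell (median -0.18, range -0.26 to -0.10; camera adjusted p = 0.435). The prolyl hydroxylase P3h2 fell 3.35-fold and the collagen chaperone Serpinh1 1.43-fold, and P3h1 rose 1.77-fold.

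The glucocorticoid receptor gene Nr3c1 was expressed at 33.54 ± 2.80 CPM without and 41.03 ± 1.65 CPM with budesonide. It rose in the edgeR test (log2 fold change 0.29 ± 0.10, SE; adjusted p = 0.0191), but not in DESeq2 (adjusted p = 0.0684), with upper quartile scaling (0.0566), with no scaling factors (0.0908), without a filter on low counts (0.0802), or without untreated replicate 1 (0.0924) or budesonide replicate 3 (0.0536). Of 23 known glucocorticoid response genes 9 rose and 2 fell, and the median was 0.03 (range -0.05 to 0.09; camera adjusted p = 0.167). Ddit4, 1 of the 2 that fell, did not pass in DESeq2 (adjusted p = 0.262) or in edgeR when any library was left out (0.0646 to 0.211). Fkbp5, a widely used glucocorticoid target, was at 111.0 ± 2.65 and 113.0 ± 5.94 CPM (log2 fold change 0.03 ± 0.07, SE; edgeR adjusted p = 0.820), and Tsc22d3 (Gilz) at 4.21 ± 1.24 and 3.76 ± 0.931 CPM. The metallothionein Mt1 rose 1.90-fold and Klf9 1.85-fold, and the cell cycle inhibitor Cdkn1c fell 2.04-fold. Pdk4 and Cebpd, singled out after their values were seen, rose by 1.82 ± 0.19 and 1.59 ± 0.18 (log2 fold change ± SE). The list was called by DESeq2 statistics (adjusted p = 0.00523) and without a filter on low counts (adjusted p = 0.0416), with a range over the alternatives by camera of 0.00523 to 0.305. By fry, which tests a list against no change, it was called higher (adjusted p = 0.00113). Among the 5 steroid receptor genes 1 rose and 2 fell, the progesterone receptor Pgr by 2.26-fold, and the list was not called (median 0.06, range -0.26 to 0.22; camera adjusted p = 0.435).

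FGF and ERK target genes gave 5 rises and 3 falls among 13 (median 0.06, range -0.03 to 0.14; camera adjusted p = 0.829), with Etv5 1.36-fold and Egr1 1.29-fold higher and Etv4 2.02-fold and Il17rd 1.78-fold lower. Notch targets gave 1 rise and 4 falls among 10 (median -0.35, range -0.43 to -0.15; camera adjusted p = 0.0839). Dll3, a somite gene, fell from 15.28 ± 1.57 to 3.54 ± 1.04 CPM and Notch3 1.34-fold, while Dll1 rose 1.38-fold. DESeq2 statistics called the Notch list lower (adjusted p = 0.0463), as did the fit without a filter on low counts (0.0336; range over the alternatives by camera 0.0336 to 0.256). Of 12 retinoic acid pathway genes 2 rose and 7 fell (median -0.77; camera adjusted p = 0.0652). The retinoic acid binding protein gene Crabp2 fell 1.72-fold, and Stra8, a retinoic acid response gene of germ cells, rose 2.13-fold. That list was called lower without a filter on low counts (adjusted p = 0.0150), with limma on the deposited normalized counts (0.0460), with a GC and length offset (0.0361) and without budesonide replicate 3 (0.0493), with a range over the alternatives by camera of 0.0150 to 0.256.

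Many markers of later cell types had too few reads to be tested. Neural and spinal cord progenitor genes gave 2 rises and 5 falls among 9 (median -0.68; camera adjusted p = 0.0719). The progenitor filament gene Nes fell from 130.9 ± 5.21 to 36.04 ± 1.96 CPM and Msi1 3.75-fold. Pax6 rose from 9.48 ± 0.803 to 16.89 ± 1.94 CPM, and Sox21, the largest of the rises named above, rose 5.83-fold. This list was called lower by DESeq2 statistics (adjusted p = 0.00346), without a filter on low counts (0.000778), with the filter at 1 CPM (0.0391), with the replicate number as a block (0.0485) and without untreated replicate 1 (0.0407), with a range over the alternatives by camera of 0.000778 to 0.256. Of 9 neuronal genes 3 rose and 4 fell (median -0.33, range -0.62 to -0.20; camera adjusted p = 0.907), with Stmn2 1.77-fold and Tubb3 2.17-fold higher and Dcx 2.63-fold lower. Neural crest genes gave 1 rise and 4 falls among 10 (median -0.39, range -0.63 to -0.30, camera adjusted p = 0.0839). Foxd3, counted above as a shared pluripotency gene as well, was 2.60-fold higher and Ets1 1.99-fold lower. That list was called lower without a filter on low counts (adjusted p = 0.0314), with the filter at 1 CPM (0.0327), without genes of more than 1 list (0.0157) and without budesonide replicate 3 (0.0493), with a range over the alternatives by camera of 0.0157 to 0.517. Of 8 surface ectoderm genes only Krt15 fell (median -0.37, range -0.50 to -0.21; camera adjusted p = 0.399), and none did adjusted over the list alone. Krt15 lost its call without a filter on low counts (adjusted p = 0.0748) and when any library other than budesonide replicate 1 was left out (0.0705 to 0.208).

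Of 8 presomitic and somitic genes 3 rose and 2 fell (median -0.38, range -0.49 to -0.21; camera adjusted p = 0.907), and 15 further members had too few reads, among them Tbx6, with 27 reads in all untreated and 16 in all budesonide libraries, and Meox1, with 16 and 20. The neural factor Sox1 had 34 and 18 reads. Of 8 cardiac and lateral plate genes Mef2c alone fell, 2.36-fold (median -0.11, range -0.22 to 0.03; camera adjusted p = 0.399). Endothelial and blood genes gave 2 rises and 1 fall among 13 (median -0.17, range -0.25 to 0.06; camera adjusted p = 0.907), and Pecam1, an adhesion molecule also made by ESCs, rose from 27.74 ± 1.16 to 81.76 ± 2.84 CPM. Tek, the other that rose, and Lmo2, which fell, did not pass in DESeq2 (adjusted p = 0.118 and 0.0780). Neither passed in edgeR without untreated replicate 2 (0.223 and 0.0645) or budesonide replicate 1 (0.0545 and 0.0670). In the list of definitive endoderm genes Foxa2 fell from 11.21 ± 2.85 to 0.811 ± 0.433 CPM, 2 of 12 fell in all and none rose (median -0.28, range -0.39 to -0.03; camera adjusted p = 0.282), and Sox17 was at 1.74 ± 0.517 and 1.42 ± 0.599 CPM. Cer1, the other that fell, lost its call without untreated replicate 1 (adjusted p = 0.0723). Extraembryonic endoderm genes gave 2 rises and 1 fall among 11 (median -0.33, range -0.47 to -0.21; camera adjusted p = 0.737), with Apoe up 2.53-fold and the laminin chain Lamb1 down 2.28-fold. Of 7 trophoblast genes Tead4 rose 1.97-fold and Cdx2, also a tailbud gene, fell (median -0.30, range -0.53 to -0.17; camera adjusted p = 0.435).

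**Figure D3:**
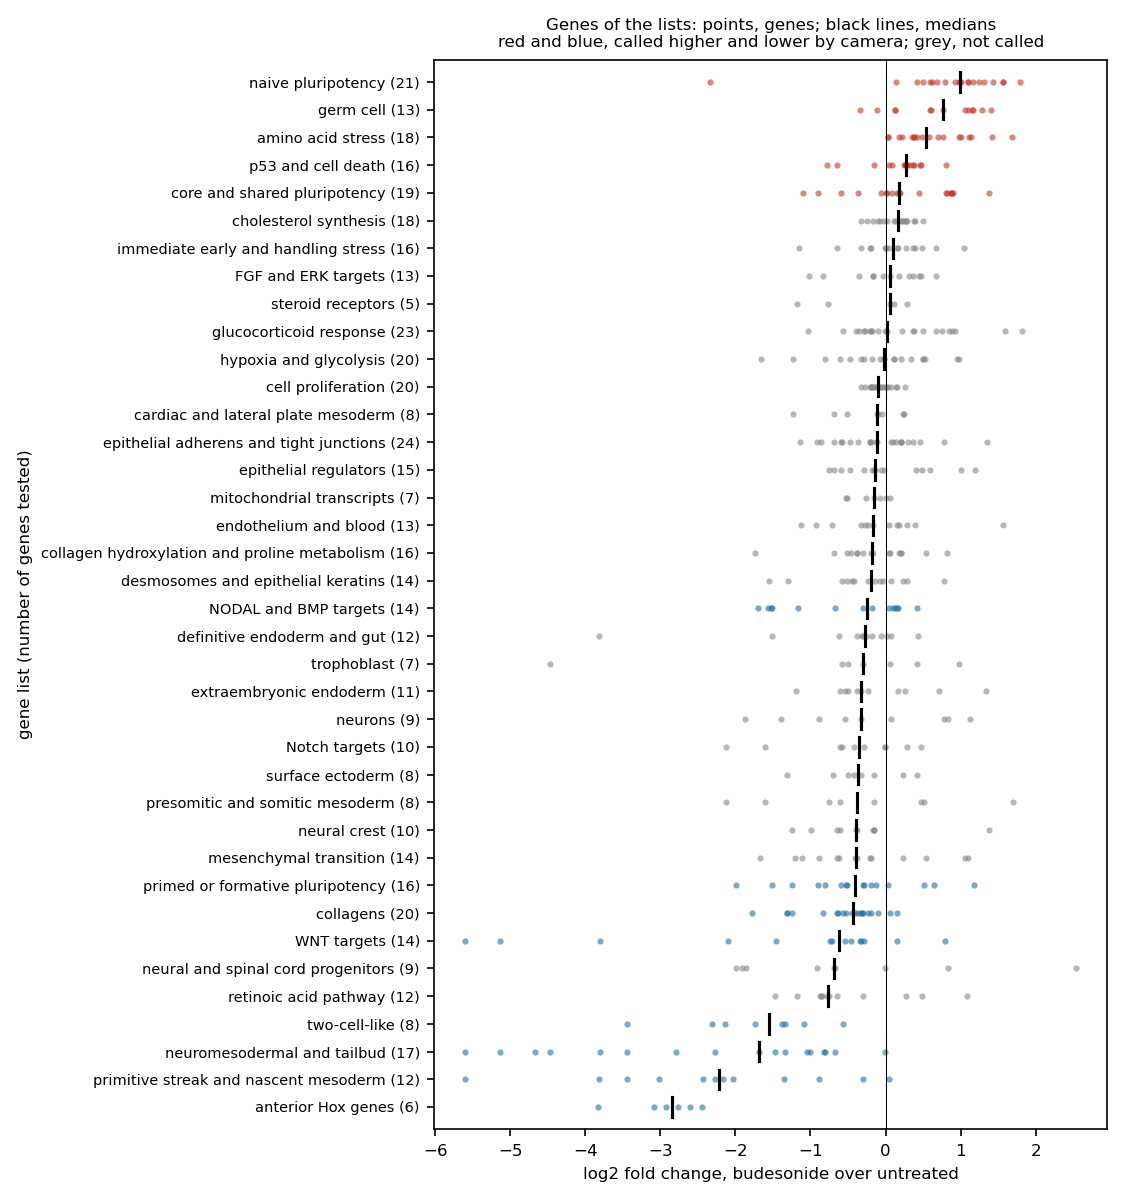
Log2 fold change, budesonide over untreated, of each tested member (points) of the 38 gene lists tested, with the list median (black line) and the number of genes tested in brackets. Lists called higher (5, red) or lower (8, blue) by camera with its preset correlation stand against those not called (grey), with medians from 0.99 for naive pluripotency to -2.84 for anterior Hox genes.

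Genes induced by amino acid shortage rose together: 15 of 18 rose and none fell, with 16 and none adjusted over the list alone (median log2 fold change 0.54; camera adjusted p = 3.43e-09; adjusted p = 0.0592 with an estimated correlation). Asparagine synthetase, Asns, rose from 93.77 ± 4.46 to 188.6 ± 6.73 CPM and the cystathionine lyase gene Cth 2.17-fold. Of 16 p53 target and cell death genes 10 rose and 2 fell (10 and 3 adjusted over the list alone; median 0.28). Trp53inp1 rose 1.74-fold and Mdm2, which limits p53, 1.38-fold, while the cell cycle inhibitor Cdkn1a fell 1.71-fold and the cell death gene Pmaip1 1.56-fold. That list was higher by camera, adjusted p = 0.0351, with adjusted p = 0.256 with an estimated correlation. The call was lost without genes of more than 1 list (adjusted p = 0.103), without untreated replicate 3 (0.0624) and without budesonide replicate 1 (0.0531). Immediate early genes gave 5 rises and 1 fall among 16 (7 and 1 adjusted over the list alone; median 0.10, range 0.01 to 0.21; camera adjusted p = 0.188), Jun 2.07-fold higher and Egr3 2.22-fold lower.

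Genes of hypoxia and glycolysis went both ways, with 6 rises and 6 falls among 20 (7 and 6 adjusted over the list alone; median -0.02, range -0.10 to 0.03; camera adjusted p = 0.907). The glucose transporter Slc2a3 rose 1.93-fold and Pdk1 1.41-fold, while lactate dehydrogenase, Ldha, fell from 440.3 ± 16.0 to 188.0 ± 8.58 CPM and Pfkl 1.53-fold. Cholesterol synthesis genes rose in 8 of 18 cases and fell in 1 (8 and 2 adjusted over the list alone; median 0.16, range 0.08 to 0.18; camera adjusted p = 0.150), with Fdft1 1.42-fold and Cyp51 1.31-fold higher. Of 20 proliferation genes 2 rose and 4 fell (median -0.10, range -0.18 to -0.06; camera adjusted p = 0.310), with Mki67 1.20-fold lower, Plk1 down from 80.06 ± 4.40 to 63.88 ± 3.41 CPM and Mcm6 1.20-fold higher. Kif11, the other that rose, lost its call without any of the untreated replicates (adjusted p from 0.0709 to 0.0980) or without budesonide replicate 1 (0.140). It also did so with upper quartile scaling (0.171).

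Of 7 mitochondrial transcripts tested 4 fell and none rose (median -0.16, range -0.24 to -0.09; camera adjusted p = 0.158), mt-Nd1 by 1.44-fold, and the list was called lower by DESeq2 statistics (adjusted p = 0.0185) and with a GC and length offset (0.0361; range over the alternatives by camera 0.0185 to 0.574). The 7 tested mitochondrial mRNAs and 6 others with at most 12 reads each over all libraries took 1.32% ± 0.0459 of the reads without and 1.11% ± 0.0921 with budesonide (SD, n = 3), so this share is in effect that of the 7. The nuclear RNA Malat1 took 1.01% ± 0.0194 and 1.58% ± 0.0244, the small nuclear RNA 7SK 0.384% ± 0.00984 and 0.544% ± 0.0158, and mitochondrial ribosomal RNA 10.29% ± 1.03 and 11.12% ± 0.914. Malat1, 7SK and the mitochondrial mRNAs each gave p = 0.1 in a two-sided exact permutation test, the smallest that 3 against 3 libraries allow, and mitochondrial ribosomal RNA gave p = 0.6. The shares of Malat1, 7SK and mitochondrial mRNA thus separated the same groups of libraries as the gene lists above.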

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

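The count of 4917 changed genes lay between 3327 (DESeq2) and 5189 (no scaling factors) under every alternative, and that of 875 genes over 2-fold between 661 (DESeq2) and 976 (without budesonide replicate 2). DESeq2 called 1321 lower genes, and 3312 of its calls were among the 4917. The number of lists called was 1 with estimated correlations (0 higher, 1 lower) and 25 with fry (8 higher, 17 lower), which tests a list against no change and not against other genes. Fry added 12 lists to those of the main test. The glucocorticoid response, cholesterol synthesis and immediate early lists were higher. The cardiac, trophoblast, neural progenitor, neural crest, desmosome, mesenchymal transition, steroid receptor, Notch and retinoic acid lists were lower. Without a filter on low counts 13 lists were lower. Leaving out 1 library gave 10 to 15 lists, with 3 to 5 higher, the 3 without budesonide replicate 1. The cause was not tested for these, except that fry asks another question. A higher within-list correlation is argued against as the reason that the germ cell and anterior Hox lists lost their calls with estimated correlations. Their estimates, -0.0497 and -0.0832, lay below the preset 0.01. Those of the other called lists ran from -0.0157 (tailbud) to 0.216 (naive). The tailbud estimate also lay below the preset, yet its camera adjusted p went from 3.15e-13 to 0.0424. The streak estimate, 0.0111, was close to the preset, and its camera adjusted p went from 6.61e-09 to 0.0592. For these lists the higher adjusted p is therefore no sign of correlated genes. For the called lists with higher estimates, the part played by correlation was not tested. The fits with a GC and length offset and with no scaling factors were chosen after seeing the data. Of 124 named genes called, none changed sign under any alternative and 13 lost the call when some library was left out. Of the lists, 4 lost and 3 gained a call when 1 library was left out, as given in the report. Over all alternatives the medians of the core pluripotency and of the NODAL and BMP lists ranged from 0.10 to 0.24 and from -0.67 to -0.15. The medians of 6 lists that were not called changed sign under some alternative, as their ranges in the report show, and the median of the glucocorticoid response list was -0.0016 without a filter on low counts, against 0.03. The replicate numbers did not pair the libraries: deviations from the group means correlated at 0.040, 0.059 and -0.018 for numbers 1, 2 and 3, and 4 of 6 libraries correlated best with their own number. With the replicate number as a block, 4986 genes changed, 866 of them over 2-fold, and 13 lists were called, not the same ones: NODAL and BMP targets lost the call (adjusted p = 0.0663) and neural and spinal cord progenitors gained it (0.0485). For each of the 13 called lists the highest adjusted p over the alternatives was that with an estimated correlation, from 0.0424 to 0.357. Depth limits the genes near 1 CPM, and calls of folds below 1.5 are incomplete. For genes under 5 CPM the recovery of changes of any fold was not simulated.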

Other observations

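Apart from the chance split of the libraries, the tests here, the GC and length offset among them, were chosen after the data were seen, and so were the gene lists of the next 2 paragraphs, for which no list test is given because some of their members had already been seen to rise.

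Targets of NRF2, the regulator of the oxidative stress response, rose in 17 of 23 tested cases and fell in 2 (median log2 fold change 0.52). The quinone reductase Nqo1 rose from 12.73 ± 2.49 to 47.84 ± 3.88 CPM (SD, n = 3), the prostaglandin reductase Ptgr1 3.15-fold and the exporter Abcc4 2.38-fold, and the ferritin chains Fth1 and Ftl1 rose 1.65-fold and 1.64-fold. The cystine transporter Slc7a11, shared with the amino acid stress list, was at 9.76 ± 1.35 and 9.91 ± 0.788 CPM. Of 14 targets of the liver X receptors, which sense oxidised cholesterol, 9 rose and 1 fell (median 0.57). The cholesterol exporters Abca1 and Abcg1 rose 4.10-fold and 2.97-fold, Apoe, also in the extraembryonic endoderm list, from 287.9 ± 7.45 to 728.0 ± 64.8 CPM and the desaturase Scd1 2.06-fold, while Scd2 was at 665.4 ± 18.7 and 695.2 ± 37.2 CPM.

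The 5 tested Rhox genes, a cluster of X-linked reproductive homeobox genes with similar copies, all rose in the edgeR test. In DESeq2 Rhox9 did not pass (adjusted p = 0.0895) and Rhox1 was given no adjusted p. The untreated means of Rhox1, Rhox6 and Rhox9, 0.792, 1.15 and 1.34 CPM, lay within the background of the receptor genes, so their folds are uncertain. Rhox13 rose from 8.68 ± 0.519 to 32.01 ± 4.60 CPM and Rhox5 from 22.79 ± 1.40 to 34.67 ± 0.946 CPM, and Rhox5, Rhox6 and Rhox9 are also in the germ cell list.

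The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of the 10, gave as many as 4917 genes by edgeR. Each of the other splits gave 0 genes at an adjusted p under 0.05 by edgeR and by DESeq2, and 197 to 531 genes at an unadjusted p under 0.05 by edgeR. All of these mix treated and untreated libraries in both groups. Any difference between the real groups then widens the spread within each and makes calls unlikely, so the 0 counts are no evidence against chance.

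The fall of streak, tailbud and anterior Hox genes with the rise of naive genes was set against 3 explanations. A trend with GC content or transcript length is argued against, since with the offset the tailbud median was -1.52 and the naive median 1.05, both lists still called (adjusted p = 0.112 for the naive list with an estimated correlation, without the offset), while the 95th percentile of the shift of single genes was 0.164 (log2). A difference in composition that moved all genes alike is argued against by the median of all tested genes with no scaling factors. It was -0.0952 (log2), against -1.77 for the tailbud list. Depth could not be tested this way, because that fit still divided by the library totals. Fewer cells of a type that lacks all naive genes, among otherwise unchanged cells, would raise all naive genes by the same fold, but the SD of their log2 fold changes was 10.3 times their median standard error, and 5.29 times without Gbx2. Loss of a cell type that makes some naive genes, a lower level per cell, a difference in collection time or vehicle between the groups, and an effect of budesonide itself stay open as hypotheses, untested in bulk RNA.

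The rise of amino acid stress genes stayed at a median of 0.62 (camera adjusted p = 2.80e-09; adjusted p = 0.0592 with an estimated correlation, without the offset) with the GC and length offset, which argues against such a trend. Stress from handling could not be decided: the immediate early genes had a median of 0.10, with an SD of 0.52 between members. The labels give no culture day or medium batch, so such a difference between the groups, and an effect of budesonide, remain open.

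Malat1, Neat1 and 7SK were 1.65-fold, 2.75-fold and 1.49-fold higher with budesonide. A higher share of nuclear RNA that raised all such RNAs alike is argued against. The summed CPM of 12 other RNAs listed as nuclear changed by -0.057 ± 0.050 (log2, SE) and their median was -0.01, with an SD of 0.41. They went both ways: Tsix, Pvt1, Snhg11 and Tug1 rose and Meg3, Kcnq1ot1 and Miat fell. The sum weighs most on Meg3 and Rian (means of 540.3 and 501.0 CPM untreated). A rise hidden by changes of single genes therefore stays open. Carry-over of RNA without poly(A) tails may contribute and cannot be told apart: the median of 12 other such RNAs was 0.41, with 5 higher and none lower, but 28 of 53 replication-dependent histone genes were lower and none higher (median -0.30), and histone mRNA also follows the cell cycle. Regulation of these genes in treated cells stays open.

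Reads on mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l numbered 11, 4, 12, 2, 4 and 0 over all 6 libraries, against 155299 on mt-Co1 and 75007 on mt-Cytb.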
